A study of Solanum lycopersicum with 28 samples.

How the data were processed

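Leaves and root tips of 2 near-isogenic tomato lines were compared on two-colour cDNA arrays, per the labels. Motelle carries the Mi resistance gene and is called the resistant line here. Moneymaker lacks it and is called the susceptible line. Leaves were exposed to potato aphid and root tips to root-knot nematode, a sedentary parasite of roots. RNA of an attacked sample and RNA of its mock-treated partner shared each array, and such a pair is called an extract pair. Attacked RNA carried Cy3 and mock RNA Cy5, per the labels, except on 4 arrays of the 6 h groups, where the same extracts were hybridised again with exchanged dyes.

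The values used were the deposited log2 ratios of the series value table, of which every column was used. The submitters' processing notes name limma, with version and role not given in the sources used here. Background correction and normalization are not given in the sources used here either. Array medians lay between -0.01 and 0, so the ratios were already centred on each array. All values below 0 lay within 0.002 of the log2 of a ratio with 2 decimals. The numerator of the ratio is not given in the sources used here.

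The table held 32448 spots, with a value in 49.5% of all spots and arrays and in 12625 to 19336 spots per array. Accessions printed at 2 spot numbers showed a regular layout, and all 905 such accessions matched it. The same layout was used to pair the other spots, which gave 15360 clones of 2 spots each. Paired spots correlated at r = 0.94 for annotated clones and r = 0.88 for the others, across clones and arrays, against 0.01 for random pairs. The available spots of a clone were averaged. The 1728 spots outside the layout held no value. Signal over background was not used here.

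The platform is a potato cDNA array, so gene symbols are those of potato. The platform annotation listed 1810 probes, of which 1630 had 1 gene symbol and 180 had several, while 30638 probes were not listed. No gene was named from a probe with several symbols. Of the clones, 157 had 1 symbol other than an LOC number, for 91 symbols in all. Potato gene IDs could not be joined to the tomato gene table, so no genome coordinates are given.

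Values of the flipped arrays correlated positively with those of their partners across clones, so the ratios were taken to run by sample and no array was turned. Ratios that run by dye were not excluded, and the dye effect described next would then hold a response. The direction of the ratio stays open. The dye effect of a clone was the mean over the 4 swap pairs of the difference between the unflipped and the flipped array, divided by 2. It was subtracted from every group with a single dye orientation, and its variance was added with the same residual spread. A swap pair was averaged to 1 value. The 24 extract pairs in 12 groups of 2 entered a single fit of group means with 12 residual degrees of freedom. Variances were moderated with limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. A clone was tested where every group of the comparison had both replicates and, where the dye effect entered, at least 3 swap pairs. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

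The labels number the replicates 1 and 2 but do not say that they came from separate plants, so p-values measure the spread between these extract pairs, which may be technical. With 2 extract pairs per group, the number of arrays limits the precision. The median SD between replicates was 0.27 on the log2 scale in leaf groups and 0.15 in root groups. The shared fit uses 1 spread for both organs. The later root time is 36 h in the treatment text of the labels and 48 h in the sample titles, and it is called 36 h here.

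Genes were named by a rule fixed before the data were examined, which spoke of gene descriptions, and symbols took their place. Clones needed an adjusted p under 0.05 and the sign of the comparison in at least 75% of extract pairs. Among those with 1 symbol other than an LOC number, the 10 largest changes in each direction were named, with 1 clone per gene. At most 2 clones without any symbol were added per direction, by clone number. Clones with an LOC number or several symbols entered neither set, which the fixed rule did not foresee. Larger changes among them are therefore not listed by this rule. Where no clone passed, the 5 smallest p-values are given. For differences between periods or lines, an extract pair counted towards the sign when it lay on that side of the mean of the other period or line.

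The 20 gene lists fixed at the same time search gene descriptions, and the annotation used here holds symbols only. None of them reached the 5 clones required, so none was tested. Lists of gene symbols were written after the symbols and the counts of calls, and before any value of a named gene, had been seen. They were tested with limma's cameraPR at a preset correlation of 0.01 and again with the correlation estimated for each list. Benjamini-Hochberg adjustment was over the lists of each comparison, and not over comparisons.

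The fit was tested on simulated data with 200 changed clones, drawn with the spread, dye effect and missing values of the real arrays. Extract pairs were drawn independently of each other, so deviations shared by same-numbered extract pairs of the lines were left out. The shares below may therefore differ from those of the real arrays. For the leaf response over both lines, 98% of clones changed by 1 on the log2 scale and 71% of those changed by 0.5 were recovered, among 5385 clones. For the leaf difference between lines these shares were 96% and 64% among 5385 clones, with 22 false calls among 182. For leaf late minus early they were 93% and 55% among 5385 clones, with 14 false calls among 162. For the root response over both lines they were 90% and 28% among 6606 clones, and for the root difference between lines 78% and 21% among 7783 clones. In the simulated leaf difference between lines 7.87% of unchanged clones had an unadjusted p under 0.05, and in late minus early 5.71%, as the shared spread understates that of leaves. The share was 1.08% for the leaf response over both lines, and 2.83% and 2.46% for resistant and susceptible leaves. It was 1.03% for the root response over both lines, and 0.889% and 0.789% for resistant and susceptible root tips. For the root difference between lines it was 1.93%. In the simulation the tests of the responses were thus stricter than their nominal level.

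Alternatives were no dye term, median-centred arrays, arrays scaled to one spread, a replicate block, separate fits of leaf and root, clones with a value on all arrays, a change of at least 2-fold, robust moderation, flipped arrays left out, all 28 arrays with a dye coefficient and a random extract pair, and each extract pair left out in turn. After seeing the data, a dye variance taken from the swap pairs themselves, a comparison of the root times and the lists of gene symbols were added.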

Results

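The data set held 28 arrays of 24 extract pairs in 12 groups of 2. Leaves of the resistant and the susceptible tomato line were compared with mock-treated leaves at 6, 12, 24 and 48 h after potato aphid infestation. Root tips of both lines were compared with mock-treated root tips at 24 h and 36 h after root-knot nematode infection, where sample titles give 48 h for the later time. The 20 leaf arrays covered 16 extract pairs and the 8 root arrays covered 8. Between 12625 and 19336 of 32448 spots had a value on an array. The comparisons ask how each line responded to attack and whether the responses of the lines differed.

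Each value is a log2 ratio within an array whose numerator was not stated. Positive and negative below refer to the sign of the deposited ratio, and fold values are sizes with no direction. Flipped arrays at 6 h correlated with their partners across clones at r = 0.32 and 0.22 in the resistant line and 0.21 and 0.28 in the susceptible line. Clones are not independent replicates. The ratios were taken to run by sample, which was not settled and on which the dye effect rests. The dye effect had an SD of 0.20 over clones, and the differences between dye orientations correlated between swap pairs at r = 0.53 to 0.81.

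In leaves over both lines and all 4 times, STUGE51, a UDP-glucose epimerase, had a log2 ratio of 0.62 ± 0.15 (SE, 16 extract pairs), a 1.54-fold change with a limma adjusted p of 0.0333. DHAR, a dehydroascorbate reductase, had 0.53 ± 0.14 with a limma adjusted p of 0.045. SHKA, which encodes the first enzyme of the shikimate pathway, had 0.46 ± 0.12 with a limma adjusted p of 0.0379. TK was negative at -0.43 ± 0.11 with a limma adjusted p of 0.044. The sign of the mean was seen in 13 of 16 extract pairs for STUGE51, 16 for DHAR, 14 for SHKA and 13 for TK. Of 2 tested clones each of STUGE51 and TK, 1 passed and both had the same sign. Unnamed clones reached larger values, with 1.82 for clone 147425 and 1.44 for clone 132346 on the positive side, and -1.46 for clone 137182 and -1.25 for clone 137858 on the negative side. In all, limma called 175 of 5385 clones, 82 positive and 93 negative. Of 9 clones of defence and oxylipin genes, SHKA alone passed, and the list had an adjusted p of 0.0531. Of 15 clones for methionine and amino acid metabolism none passed over all clones, 7 passed on the positive side when adjusted over the list alone, and the list had an adjusted p of 0.0531. The count was 27 with leaf and root fitted separately, where STUGE51, DHAR, SHKA, TK and clones 147425 and 137858 did not pass, 103 with arrays scaled to one spread, where SHKA and TK did not pass, and 2569 without the dye term. With 1 extract pair left out, STUGE51 passed in 12 of 16 fits, SHKA in 8, TK in 7 and DHAR in 5, and the count was 24 to 53 without a 6 h extract pair and 641, 320 and 284 without replicate 1 of resistant 12 h, resistant 48 h and susceptible 24 h. With the replicate number as a block, DHAR and TK did not pass, with limma adjusted p of 0.0526 and 0.0513.

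**Figure D1:**
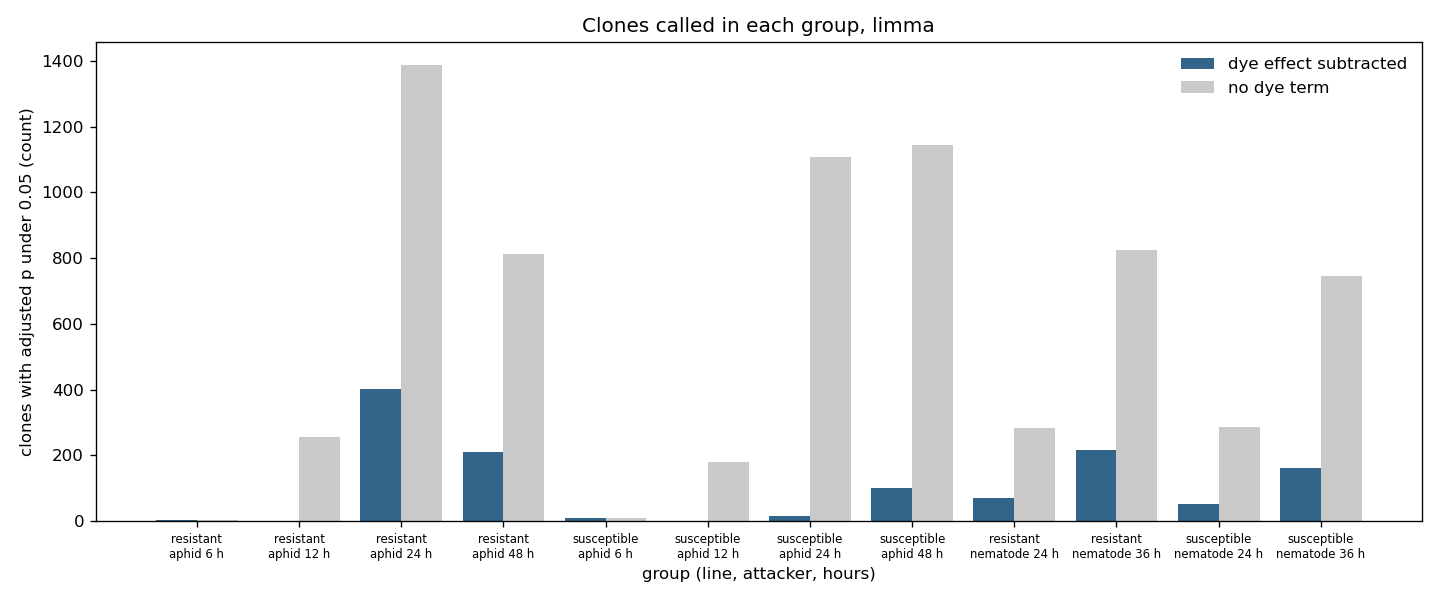
Number of clones with a limma adjusted p under 0.05 (vertical axis) in each of the 12 groups (horizontal axis), with the dye effect subtracted and its variance added (blue bars) and without a dye term (grey bars). The resistant leaf group at 24 h had 401 calls with the dye term and 1387 without it.

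In leaves of the resistant line, limma called 61 of 5785 clones, 30 positive and 31 negative. Of 100 splits that turned the signs of extract pairs at random, the real one included, 7 gave as many, so chance cannot be excluded for that count. In leaves of the susceptible line it called 54 of 6024, 30 positive and 24 negative. Defence and oxylipin genes of the resistant line stood on the positive side of other clones, with an adjusted p of 0.0133 over 10 clones. The value was an adjusted p of 0.0657 with an estimated correlation. None of these clones passed alone, with 0.49 ± 0.13 for SHKA and 0.57 ± 0.16 for PPO, a polyphenol oxidase. In the susceptible line the list lay on the positive side too, with a cameraPR adjusted p of 0.163 over 9 clones. For the leaf difference between the lines its cameraPR adjusted p was 0.9455, so a shift particular to the resistant line was not shown. The list for methionine and amino acid metabolism also had an adjusted p of 0.0133 in the resistant line, and an adjusted p of 0.431 with an estimated correlation. Without the dye term the adjusted p of that list was 0.655. With the dye term that list had a cameraPR adjusted p of 0.35 in the susceptible line and 0.141 for the leaf difference between the lines. Its 15 clones covered 4 genes, and 8 of them were METK1, an S-adenosylmethionine synthetase, with log2 ratios from 0.41 to 0.94 that did not pass. Fitted separately from root, the counts were 0 in the resistant and 1 in the susceptible line, and without the dye term 1593 and 1860. With arrays scaled to one spread they were 32, of which 10 were positive, and 20, of which 9 were positive.

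Late minus early compared the mean of 24 and 48 h with the mean of 6 and 12 h over both lines. PR1B, a pathogenesis-related protein, had the largest named difference, with 2.67 ± 0.51 in clone 159490 (limma adjusted p = 0.00296, 15 of 16 extract pairs) and 2.46 ± 0.42 in clone 147859. In clone 159490 it ran from -2.33 ± 0.86 (SD, n = 2) at 6 h to 2.07 ± 0.14 at 48 h in the resistant line, and from -0.93 ± 1.46 to 3.40 ± 0.70 in the susceptible line. PSBR, a photosystem II protein, had a difference of -0.96 ± 0.24 in clone 150316, and THF1, which is needed for thylakoid formation, had -0.58 ± 0.11. All 3 tested PSBR clones had a negative difference, of which 1 passed. In clone 150316 the means at 6, 12, 24 and 48 h were 0.725, 0.50, -0.88 and -0.95 in the resistant line. They were 0.45, 0.54, 0.52 and -0.31 in the susceptible line, where the 24 h mean thus stood near the early ones. DHAR2 had -0.79 ± 0.20 and TK had -0.76 ± 0.16, and both tested clones of each passed.

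On the positive side stood GAPDH of glycolysis with 0.78 ± 0.15, the catalase CAT1 with 0.72 ± 0.18, PPA1 with 0.64 ± 0.15 and SHKA with 0.57 ± 0.14. RSI5 had 0.86 ± 0.28, the mitochondrial uncoupling protein UCP 0.46 ± 0.15, SS16 0.40 ± 0.12 and the protein kinase PKIN1 0.39 ± 0.12. Not every late mean lay above every early one. CAT1 clone 152782 had means of 0.02 and 0.12 at 24 h in the resistant and susceptible line, against 0.09 and 0.13 at 6 h. PKIN1 stood at 0.06 at 48 h in the susceptible line, against 0.265 at 6 h. Of 7 GAPDH clones, 7 were positive and 2 passed, while 1 of 2 CAT1 clones and 2 of 3 SS16 clones were positive. Clones 142403 and 148029, which have no name here, had 3.00 ± 0.46 and 2.53 ± 0.30, and clones 156313 and 147994 had -2.24 ± 0.53 and -1.99 ± 0.55. Of 9 clones of defence and oxylipin genes, 3 passed on the positive side, namely both PR1B clones and SHKA, and 6 did not pass. The list had an adjusted p of 0.00577, and an adjusted p of 0.0171 with an estimated correlation. Of 7 clones of redox and alternative respiration genes, 2 passed on the positive side, 2 passed on the negative side and 3 did not pass, and the list had an adjusted p of 0.605. In all, limma called 948 of 5385 clones, 416 positive and 532 negative. The count was 514 with leaf and root fitted separately, where RSI5, SHKA, UCP, SS16, PKIN1 and clone 147994 did not pass, while UCP did not pass without the dye term and RSI5, SS16 and PKIN1 did not pass with arrays scaled to one spread. It was 1549 without resistant 12 h replicate 2 and 614 without susceptible 6 h replicate 1, and with 1 extract pair left out RSI5 passed in 8 of 16 fits, UCP in 7, SS16 and PKIN1 in 4 and PSBR in 15.

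**Figure D2:**
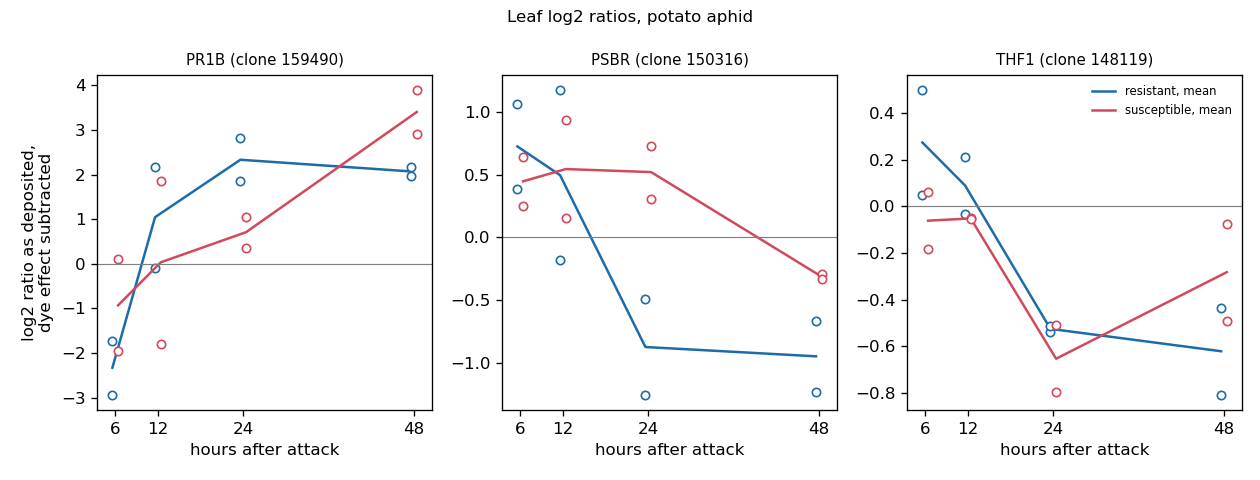
Log2 ratio with the dye effect subtracted (vertical axis) against hours after aphid infestation (horizontal axis) for PR1B, PSBR and THF1. Open circles are the 2 extract pairs of a group and lines join their means, in blue for the resistant and red for the susceptible line. PR1B had its highest mean, 3.40, at 48 h in the susceptible line.

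At single times in the resistant line, limma called 3 clones at 6 h, 0 at 12 h, 401 at 24 h and 209 at 48 h, where 532 clones at 12 h had an unadjusted p under 0.05. Of the 209 calls at 48 h, 47 were positive. In the susceptible line it called 9 clones at 6 h, 0 at 12 h, 16 at 24 h and 99 at 48 h, with 291 at an unadjusted p under 0.05 at 12 h. The 2 replicates correlated across clones at 0.136, -0.099, 0.617 and 0.681 at 6, 12, 24 and 48 h in the resistant line. In the susceptible line they correlated at 0.252, 0.099, 0.414 and 0.607. The replicates thus agreed little at 6 and 12 h, and the low counts there do not show that the response was small. Same-numbered extract pairs of the lines correlated more, at 0.579 and 0.277 at 6 h for replicates 1 and 2. At 12 h these values were 0.539 and 0.272, so extract pairs of the lines may not vary independently. PR1B passed at 48 h in the susceptible line, with limma adjusted p of 0.0457 and 0.0302 for clones 159490 and 147859. In that order they did not pass with arrays scaled to one spread (limma adjusted p of 0.139 and 0.117) or with leaf and root fitted separately (0.17 and 0.0822), and they passed in 4 and 6 of 8 fits with 1 extract pair left out. Its means in the resistant line at 48 h were 2.07 and 1.82, with limma adjusted p of 0.196 and 0.169, and there both clones passed without the dye term. With arrays scaled to one spread the order of 24 and 48 h turned in the resistant line, with 25 and 292 calls, while the susceptible line had 3 and 12, and the 6 h counts were 5 and 17. Fitted separately from root, the calls were 26 at 24 h in the resistant line, and 1 at 24 h and 10 at 48 h in the susceptible line. With replicate 1 or 2 of the group itself left out, the counts in the resistant line were 1 and 42 at 6 h, 24 and 44 at 12 h, 31 and 232 at 24 h, and 343 and 0 at 48 h. In the susceptible line they were 1 and 1, 6 and 1, 70 and 29, and 25 and 18 at the same times. Summed over times, the calls were 613 and 124. Fitted separately the sums were 26 and 11, and with arrays scaled to one spread 322, of which 78 were positive, and 32, of which 12 were positive. They were 2456 and 2437 without the dye term, 2504 and 2609 with flipped arrays also left out, 1452 and 1018 with all arrays and a dye coefficient, and 1450 and 912 with a dye variance from the swap differences, so the lines' counts lay closer in ratio in these settings and their order turned in the second.

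The difference between the responses of the lines is the question of the design. In leaves, limma called 0 of 5385 clones for resistant minus susceptible, with 200 at an unadjusted p under 0.05. The median 95% interval of a clone reached 0.25 on either side on the log2 scale. The smallest p-values, none of which passed, belonged to clones without a name. They had differences of -0.47 ± 0.11 for clone 148366, 0.33 ± 0.08 for clone 156888, 0.56 ± 0.14 for clone 161183, 0.38 ± 0.10 for clone 132091 and -0.42 ± 0.12 for clone 157334. At 6, 12, 24 and 48 h taken alone, limma called 0 clones, with 67, 227, 280 and 333 at an unadjusted p under 0.05. Same-numbered extract pairs of the lines were not matched within a time, so the spread used here is an unpaired one. These counts do not show that the lines responded alike.

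In root tips over both lines and both times, NAC2, a transcription factor of the NAC family, had a log2 ratio of 1.60 ± 0.24 (SE, 8 extract pairs), a 3.03-fold change with a limma adjusted p of 0.000411. STUGE51 had 1.06 ± 0.20 with a limma adjusted p of 0.00368, and both of its clones passed. The alcohol dehydrogenase ADH1 had 0.71 ± 0.17 with a limma adjusted p of 0.0329. All 3 genes were positive in 8 of 8 extract pairs. NAC2 reached 2.27 ± 0.10 (SD, n = 2) at 36 h in the resistant line and 1.67 ± 0.01 in the susceptible line. Clones 153219 and 141055, without a name, had 2.31 ± 0.23 and 2.29 ± 0.22, and clones 136677 and 140436 had -2.26 ± 0.16 and -2.01 ± 0.18. In all, limma called 245 of 6606 clones, 175 positive and 70 negative. Of 11 clones of defence and oxylipin genes NAC2 alone passed, with an adjusted p of 0.0417 for the list and an adjusted p of 0.0979 with an estimated correlation. With the replicate number as a block the list had an adjusted p of 0.0521. HPL, a hydroperoxide lyase, had 0.35 ± 0.11 and PPO 0.44 ± 0.19, which did not pass. The count was 714 with root fitted separately, 450 with arrays scaled to one spread and 2185 without the dye term. The dye effect was measured on leaf arrays, as no root array was flipped, and ADH1 passed in 2 of the 8 fits with 1 root extract pair left out.

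**Figure D3:**
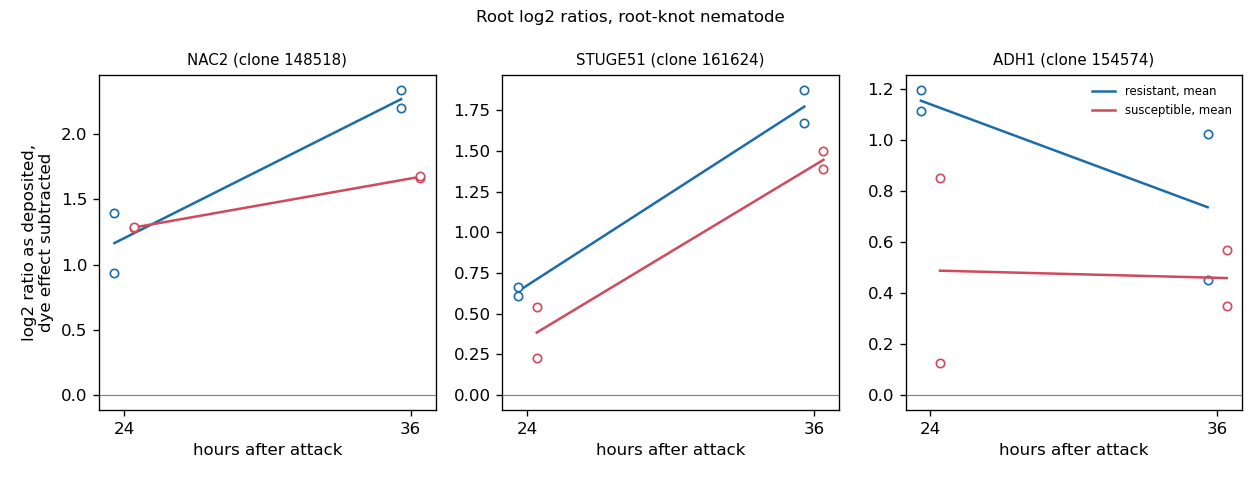
Log2 ratio with the dye effect subtracted (vertical axis) against hours after nematode infection (horizontal axis) for NAC2, STUGE51 and ADH1. Open circles are the 2 extract pairs of a group and lines join their means, in blue for the resistant and red for the susceptible line. STUGE51 stood at 0.64 and 1.77 at the successive times in the resistant line and at 0.38 and 1.45 in the susceptible line.

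In root tips of the resistant line limma called 211 of 6724 clones, 163 positive and 48 negative, and in the susceptible line 146 of 6789, 109 positive and 37 negative. At single times it called 70 clones at 24 h and 217 at 36 h in the resistant line, and 53 and 162 in the susceptible line. NAC2 passed at 36 h in both lines, with limma adjusted p of 0.000481 and 0.0108, and so did STUGE51, with 0.000943 and 0.00909 in clone 161624. In the susceptible line each of these 2 clones passed in 2 of 4 fits with 1 root extract pair of that line left out. With arrays scaled to one spread the single-time counts were 219 and 261 in the resistant and 157 and 252 in the susceptible line, and with root fitted separately 245 and 586, and 158 and 598. With replicate 1 or 2 of the group itself left out they were 13 and 5 at 24 h and 93 and 130 at 36 h in the resistant line, and 14 and 0 at 24 h and 33 and 86 at 36 h in the susceptible line. Fitted separately, the counts for the lines were 581 and 476, with arrays scaled to one spread 351 and 290, and without the dye term 1081 and 1174. Summed over times, the calls were 287 and 215, against 831 and 756 when fitted separately and 1108 and 1031 without the dye term.

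For root tips of the resistant minus the susceptible line, limma called 0 of 7783 clones, with 104 at an unadjusted p under 0.05. The median 95% interval of a clone reached 0.35 on either side. The smallest p-values belonged to clone 142475 with 1.13 ± 0.16, clone 159334 with 0.67 ± 0.14, clone 153537 with 0.70 ± 0.17, clone 140565 with 0.70 ± 0.18 and clone 142827 with -0.68 ± 0.17, none of which passed. At 24 h and 36 h taken alone, limma called 0 clones, with 52 and 184 at an unadjusted p under 0.05. Redox and alternative respiration genes had a higher difference than other clones, with an adjusted p of 0.0496 over 10 clones, and an adjusted p of 0.0355 with an estimated correlation. That estimate was 0, below the preset 0.01, so the second value comes from the less strict test. The adjustment covered the lists of this comparison only. The list did not pass with the replicate number as a block, with an adjusted p of 0.0737. None of these clones passed alone, with 0.39 ± 0.15 for the glutaredoxin GRX2 and 0.38 ± 0.22 for DHAR.

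**Figure D4:**
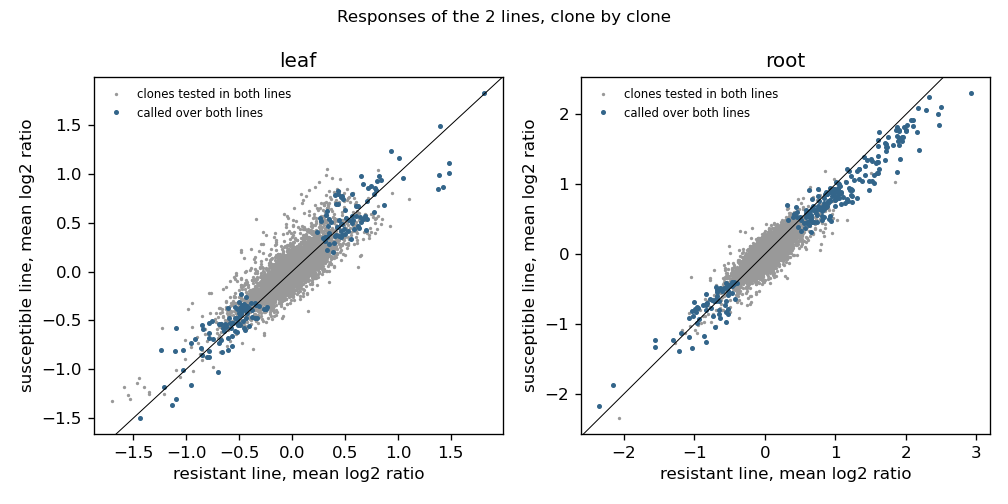
Mean log2 ratio of each clone in the susceptible line (vertical axis) against the resistant line (horizontal axis), in leaves and root tips. Grey points are clones tested in both lines, blue points are those called over both lines, and the line marks equal values. The correlation was 0.85 in leaves and 0.90 in root tips.

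Responses of the lines correlated across clones at r = 0.85 in leaves and 0.90 in root tips, where clones are not independent replicates. Both lines share the dye effect, and simulated unchanged groups with that shared estimate gave r = 0.12 and 0.11. The simulation drew every extract pair independently, with a spread pooled over both organs. Deviations shared by same-numbered extract pairs of the lines are therefore missing from it. The covariance was 0.0557 in leaves and 0.0811 in root tips, against 0.00134 and 0.00224 in the simulation. With the dye effect taken from separate swap pairs for each line, r was 0.77 and 0.86. In root tips 100 clones were called positive and 27 negative in both lines, against 2.62 and 0.27 for independent lists. In leaves these were 10 and 15, against 0.15 and 0.11. With separate swap pairs no leaf clone was called in both lines, and in root tips 58 were called positive and 7 negative in both. A dye effect from 2 in place of 4 swap pairs adds more variance to each call.

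The leaf and root responses over both lines shared 21 calls, all positive, among 5002 clones tested in both, against 1.98 for independent lists. The simulation had 0 shared calls, but its groups were unchanged and leave hardly any clone to call. That 0 is therefore no reference for the 21. STUGE51 was among the genes called in both. The correlation across clones was 0.36, against 0.20 in the simulation, and the covariance 0.0226 against 0.00169. With separate swap pairs for leaf and root r was 0.33 and no clone was called in both, again with 2 swap pairs in place of 4. The shared calls numbered 4 with separate fits and 695 without the dye term.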

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

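The tests of the dye effect, of ratios by dye with a shared response, of resistant 12 h replicate 2 and of the root times were chosen after the results were seen. The test of same-numbered extract pairs turned together was added after the leaf count was seen and before its own outcome was. The test of whether ratios run by dye was written before the correlations of the swap sums were seen, when those of the swap differences had been.

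Differences between times were tested directly in leaves. Late minus early gave 948 calls, more than the highest of the other 99 regroupings of times within lines, which gave 758, so that 1 of 100 splits gave as many. The named differences were 2.67 for PR1B, 0.86 for RSI5, 0.78 for GAPDH, 0.72 for CAT1, 0.64 for PPA1, 0.57 for SHKA, 0.46 for UCP, 0.40 for SS16 and 0.39 for PKIN1. On the negative side they were -0.96 for PSBR, -0.79 for DHAR2, -0.76 for TK and -0.58 for THF1. The list of defence and oxylipin genes differed between early and late with an adjusted p of 0.00577. In root tips 31 clones differed between 36 h and 24 h, with 1.10 for STUGE51. Regrouping the root times gave as many calls in 1 of 18 splits, with 0 as the highest other, and 18 splits are too few for a share under 0.05. Between the lines, redox and alternative respiration genes differed in root tips with an adjusted p of 0.0496, and did not pass with the replicate number as a block, with an adjusted p of 0.0737.

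Fewer clones were called with the dye term, for example 245 of 6606 against 2185 of 7783 for the root response over both lines. The term subtracts the dye effect and adds its variance, and with a variance taken from the swap differences the count was 698, so part of the drop comes from the added variance. Root RNA was on no flipped array, and of the root calls made without the dye term, 83.1% had the sign of the dye effect of the leaf arrays, consistent with a dye effect behind many of them. With ratios that run by sample, a response cancels in the difference of a swap pair, so a response shared by leaf and root would not give this match.

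Flipped arrays correlated above 0 with their partners, which could also arise if ratios ran by dye and the dye effect outweighed the response. The sum of a swap pair, and not its difference, would then carry the dye effect into root arrays. Across clones the difference correlated with the means of the 4 root groups at 0.49 to 0.64 and the sum at 0.15 to 0.26, lower by at least 0.239 in each group, which argues against that explanation. Ratios that run by dye together with a response shared by leaf and root would give these correlations too, and a slope of the sum near 1 in root tips. Slopes of the sum ran from -0.15 to 0.585, and those of the difference from 0.701 to 1.36. The slopes of the sum argue against this explanation. The highest was above the 0.5 set as the bound for excluding it, so it stays open. The numerator of the ratio stays open too, and no biological explanation was tested.

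Resistant 12 h replicate 2 correlated across clones with the mean of the 24 h extract pairs at r = 0.68 and with that of the other 12 h pairs at 0.09. PR1B stood at 2.18 there and at -0.09 in replicate 1. A swap with a late extract pair would leave a late pair that resembles early ones, and 0 of 8 late leaf pairs did. Its highest correlation with a late mean exceeded that with an early mean by 0.586, as an earlier response or a single wrong label would both give, so these cannot be told apart with 1 extract pair. Late minus early gave 1549 calls without it.

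Other splits of the samples bear on the counts. Turning the signs of extract pairs at random gave as many calls as the real signs in 1 of 100 splits for leaves over both lines (175 against a highest other of 0). The share was 1 of 100 too for susceptible leaves (54 against 5) and for root tips over both lines (245 against 60). Chance would be an unlikely source there if extract pairs varied independently. That condition was not shown, as leaf deviations of same-numbered extract pairs of the lines correlated at up to 0.34. These splits also do not probe an error in the dye effect that the groups share. With same-numbered extract pairs of the lines turned together, 4 of 100 splits gave as many leaf calls over both lines (175 against a highest other of 420), a share still under 0.05. For resistant leaves 7 of 100 splits gave as many (61 against 652), so chance cannot be excluded. The split with 652 calls set the 4 late extract pairs and 12 h replicate 2 against the other 3 early ones, which may point to a structure of the samples. Of the 7 splits with as many calls as the real signs, 1 parted late from early in at least 7 of 8 extract pairs. Of all 100 splits 8 had that parting, with 0 to 652 calls, so the parting alone did not give a high count. The highest split without that parting had 485 calls. Splits that part fewer extract pairs this way were not examined, so whether this structure lies behind the others is not known. For root tips of each line 8 splits are too few for a share under 0.05, with 1 split as large, 211 against 0 in the resistant and 146 against 1 in the susceptible line. For resistant minus susceptible the count observed was 0, which all 100 leaf splits and all 18 root splits reach by construction, so they say nothing about the lines. The highest leaf split, with 303 calls, parted replicate 1 from replicate 2, where the replicate block gave 0 calls between the lines.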

How the results depend on the processing

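The dye variance from the swap differences, the comparison of root times and the lists of gene symbols were chosen after seeing the data, the lists after the counts of calls and before any value of a named gene. The replicate block gave counts within 1.5 times of those reported, except that 3 in place of 5 gene lists passed and that single-time leaf counts became 1 in place of 0 at 12 h in the resistant and 48 in place of 16 at 24 h in the susceptible line. The lists that did not pass with the block were defence and oxylipin genes in root tips over both lines (adjusted p = 0.0521) and redox and alternative respiration genes between the lines in root tips (adjusted p = 0.0737). Deviations of same-numbered extract pairs of the lines correlated at 0.25, 0.21, 0.34 and 0.05 at 6, 12, 24 and 48 h in leaves. In root tips they correlated at 0.20 and -0.12. The numbers were not taken to pair the extract pairs, though the leaf values at 6, 12 and 24 h leave pairing there open. No fit matched same-numbered extract pairs of the lines within each time. The 0 calls between the lines in leaves therefore rest on an unpaired spread. In leaves, parting replicate 1 from replicate 2 gave 303 calls, which points to a structure of the leaf samples that follows the number. DHAR and TK in leaves and clone 151713 between root times did not pass with the block, which ended no other call of a named gene. Of the 5 called lists, 2 passed with an estimated correlation, which was 0 for redox and alternative respiration genes and so less strict there than the preset 0.01. Of the 12 single-time counts, 10 moved by over 1.5 times without a dye term, 12 with flipped arrays also left out, 10 with all arrays and a dye coefficient, 9 with the added dye variance, 10 with separate fits, 8 with scaled arrays, 3 over clones with a value on all arrays and 2 for a change of at least 2-fold. Median-centred arrays and robust moderation moved no count by over 1.5 times, and no named gene changed sign in any setting. By limma, resistant minus susceptible gave 0 calls in leaves and in root tips under every setting with all extract pairs, with 200 and 104 clones at an unadjusted p under 0.05. Signal over background was not used here. Apart from the root count over both lines without the dye term, the cause was not tested for any count that moved.

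Counts that moved are given in the order leaf response over both lines, resistant and susceptible, then root response over both lines, resistant and susceptible, then single times of resistant leaf, susceptible leaf, resistant root and susceptible root, then the overlap of leaf and root. Without a dye term they were 2569, 1593, 1860, 2185, 1081, 1174, 2456, 2437, 1108, 1031 and 695. With flipped arrays left out and no dye term they were 2871, 1977, 2155, 2105, 1012, 1081, 2504, 2609, 1038, 952 and 774. All arrays with a dye coefficient and a random extract pair gave 1653, 972, 916, 718, 393, 305, 1452, 1018, 434, 359 and 210, and 14 for root 36 h minus 24 h. The added dye variance gave 1601, 880, 791, 698, 408, 320, 1450, 912, 448, 372 and 203. Leaf and root fitted separately gave 27, 0, 1, 714, 581, 476, 26, 11, 831, 756 and 4, with 514 for late minus early and 75 for the root times. Arrays scaled to one spread gave 103, 32, 20, 450, 351, 290, 322, 32, 480 and 409, with the overlap within 1.5 times, and 15 for the root times, of which 3 were positive in place of 10 of 31. A change of at least 2-fold gave 17, 14, 10, 90, 110 and 74, then 373 for single times of resistant leaf, 2 for the overlap and 136 for late minus early. Clones with a value on all arrays gave 138 for resistant root and 0 for the root times.

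Leaving out each extract pair in turn assumes that a lone extract pair varies like the other groups. Leaf counts over both lines ranged from 24 to 641, with 42 and 50 without resistant 6 h replicates 1 and 2, 24 and 53 without susceptible 6 h replicates 1 and 2, and 641, 320 and 284 without replicate 1 of resistant 12 h, resistant 48 h and susceptible 24 h. Resistant leaf counts ranged from 0 to 696, with 0 and 20 without 6 h replicates 1 and 2, 696 without 12 h replicate 1, 22 without 24 h replicate 1, and 263 and 14 without 48 h replicates 1 and 2. Susceptible leaf counts ranged from 4 to 154, with 5 and 4 without 6 h, 127 and 15 without 12 h and 29 and 25 without 48 h replicates 1 and 2, and 154 without 24 h replicate 1. Late minus early ranged from 614 without susceptible 6 h replicate 1 to 1549 without resistant 12 h replicate 2. Single times of resistant leaf ranged from 223 to 1102, with 300 and 323 without 6 h and 1082 and 1102 without 12 h replicates 1 and 2, and 223 without 24 h replicate 1. Those of susceptible leaf ranged from 49 to 218, with 62 and 57 without 6 h and 56 and 49 without 48 h replicates 1 and 2, and 218 without 24 h replicate 1. The overlap ranged from 4 to 48, with 7 and 8 without resistant 6 h, 43 and 48 without resistant 12 h and 4 and 8 without susceptible 6 h replicates 1 and 2, and 33 without susceptible 24 h replicate 1.

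Root counts over both lines ranged from 196 to 230 with 1 extract pair left out. Those of the resistant line ranged from 139, without 24 h replicate 2, to 169, and those of the susceptible line from 81 to 119, with 88 without 36 h replicate 1 and 81 without 24 h replicate 2. Single times of resistant root ranged from 164, without 36 h replicate 1, to 215. Those of susceptible root ranged from 80 to 151, with 80 and 133 without 36 h replicates 1 and 2 and 137 without 24 h replicate 2. The root times ranged from 6 to 21, with 8 without resistant 24 h replicate 1, 6 and 17 without resistant 36 h replicates 1 and 2, 9 and 10 without susceptible 24 h and 10 and 13 without susceptible 36 h replicates 1 and 2. Resistant minus susceptible ranged from 0 to 1, with 1 call in leaves without susceptible 12 h replicate 1 and 1 in root tips without resistant 36 h replicate 1.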

Other observations

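The comparison of root times was added after seeing the data. Root tips at 36 h minus 24 h, over both lines, gave 31 calls by limma among 7783 clones, 10 positive and 21 negative, with no dye effect in the difference. STUGE51 had a difference of 1.10 ± 0.23 (SE, 8 extract pairs) with a limma adjusted p of 0.0489, and both of its clones passed. It did not pass in any of the 8 fits with 1 root extract pair left out, where its adjusted p by limma ran from 0.118 to 0.291. Its adjusted p by limma was 0.0501 with median-centred arrays, 0.167 over clones with a value on all arrays and 0.214 with all arrays, a dye coefficient and a random extract pair. Clones 134080 and 151713, without a name, had 1.92 ± 0.23 and 1.54 ± 0.31, and clones 157153 and 161171 had -1.80 ± 0.15 and -1.74 ± 0.15. Clones 157153 and 161171 passed in all 8 of those fits, clone 134080 in 3 and clone 151713 in 1. With arrays scaled to one spread neither clone 134080 nor clone 151713 passed, with limma adjusted p of 0.301 and 0.202, and clone 151713 had an adjusted p by limma of 0.0538 with the replicate number as a block and 0.131 over clones with a value on all arrays. In leaves STUGE51 had means of 0.95 at 24 h and 0.17 at 48 h in the resistant line, and 1.37 and -0.28 in the susceptible line. The difference between these leaf times was not tested alone.

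Several genes known only by an LOC number in the annotation were called in more than 1 clone, and they were chosen after their values were seen. LOC102587499 passed on the positive side in 5 of 7 tested clones in leaves over both lines, with log2 ratios from 0.33 to 1.15 over the 7, and in 4 of 9 in root tips, with 0.018 to 1.04 over the 9. For late minus early 4 of its 7 tested clones passed on the positive side and 3 were negative, from -0.33 to 1.27. Its clones thus did not share 1 time course. LOC102577434 was negative in all 5 tested clones for late minus early, from -1.06 to -0.62. LOC102577529 had -1.74 and -1.52 in the same comparison, and LOC102577893 had 1.83 and 2.04.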
